A study of Mus musculus with 2 samples.

How the data were processed

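The data are 2 RNA-seq libraries of adult mouse thymus (8 weeks, strain C57BL/6J), named biological replicates 1 and 2 in the labels. Per the labels, the libraries are stranded, made from rRNA-depleted polyadenylated RNA longer than 200 nucleotides, sequenced as paired reads of 76 bases on an Illumina GAIIx, with added spike-in RNAs. The labels give separate biosamples but 1 donor entry for both, and say littermates were used, so the spread between libraries is that between these samples, which may be technical in part.

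The authors deposited a gene table and a transcript table per library. Per the file headers these hold expected counts (estimated fragments per feature, not normalised), posterior mean counts, and TPM, which the deposited files scale to the same sum in each library over all features, spike-ins included. Per the text files deposited with them, features were quantified on mm10 with GENCODE annotation M4. The quantifier, the aligner and their versions are not given in the sources used here, nor how reads shared by several features were split. The deposited bounds of the TPM interval and the gene lengths (in TPM and bases, per the file headers) were used only as descriptions. The authors also deposited series-level lists of contigs and splice junctions on mm9, with no header. In them, the deposited score columns hold a level and a reproducibility value, and the deposited junction counts are whole numbers of reads, and these meanings were read from the values. The names of the junctions also hold 2 per-replicate entries that no label ties to a sample, and these were not used. The authors' scores were used only to rank and filter within each list.

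The gene table has 69691 features: 43346 genes, 96 spike-ins, 1 phiX control and 26248 features with numeric IDs, which had 0 counts in both libraries. Symbols, gene classes and coordinates came from GENCODE M21 (GRCm38, the build of the tables but another release), matched on the gene ID without its version, and 42462 genes matched. Of 463 list symbols, 3 were matched through RefSeq synonyms and 7 were not matched. Expected counts were rounded to whole numbers for count tests. Genes of near-identical copies share reads by a model and are uncertain.

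Depth was 49.3 and 63.1 M fragments over all features, and 48.6 and 62.1 M over genes. The median chi-square of the counts of 14794 genes was 8.93, against 0.455 for sampling noise, so the libraries were counted as separate. A count of 0 was given a floor of 3 counts per library.

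Detection used a mean TPM of at least 1. List levels are medians of mean TPM, set beside 10000 random lists of equal size from genes with at least 0.1 TPM. List ratios are medians of log2 TPM ratios (replicate 2 over replicate 1, pseudocount 0.1) of members with at least 1 TPM, set beside 10000 random lists matched on mean expression in 20 bins. List pairs were compared on log2(TPM + 1) by two-sided permutation tests across genes (exact where a list had fewer than 10 genes, otherwise 100000 resamples), with Benjamini-Hochberg adjustment over 6 pairs and genes in both lists left out. Agreement used log2(TPM + 1). Fold changes on such scales understate low genes. Differing genes were found with a two-sided exact binomial test of counts against library sizes scaled by edgeR's TMM, over genes kept by filterByExpr, at an adjusted p under 0.05 and a log2 ratio of at least 1 in size. The test covers counting error between 2 libraries only. The biological coefficient of variation is the square root of edgeR's common dispersion, estimated from these same 2 libraries as 1 group. The negative binomial test between the libraries used this dispersion, so its p-values do not measure spread among replicates. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

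Both procedures were tested on simulated data. For counts simulated for 17198 genes with a coefficient of variation of 0.214, the binomial test recovered 82% of genes changed 2.5-fold and 100% changed 4-fold with 631 false calls, and the negative binomial test 14% and 50% with 0 false calls. At a coefficient of 0.15, the binomial test recovered 96% and 100% of these genes with 134 false calls. The negative binomial test then recovered 20% and 88% with 0 false calls. The common dispersion gave a coefficient of 0.254 for the counts simulated at 0.214 and of 0.206 for those at 0.15. It gave 0.141 when only the changed genes varied beyond counting error, so genes that differ raise the estimate. The binomial calls can thus include genes that vary at the typical spread. For ratios simulated for 14280 genes, lists of 15 genes shifted by 0.5 on the log2 scale left the middle 95% in 100% of cases, and unshifted ones in 7.50%. Members of these lists were drawn from the more highly expressed genes, with noise independent between genes. The rates thus do not cover lists near 1 TPM or lists whose members vary together.

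The 35 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 15 highest genes by mean TPM outside mitochondrial and ribosomal protein genes, up to 5 of the highest members per list, all members of the receptor and sex-linked lists, 5 genes per direction among called genes with a mean count of at least 50, the 10 highest long non-coding genes, isoform genes at 10 TPM or more, 5 Trbv segments, and the 5 strongest contigs and junctions. Some genes that the rule names are not reported here. The heart and liver lists were written after the data were seen, and for the second list of each organ genes whose ratios had been read were left out. Alternatives were other scalings (DESeq2 size factors, total counts, spike-ins), filters, pseudocounts, posterior mean values, abundances without length scaling, a negative binomial test and leaving out each replicate. The coefficient of variation has no spread between replicates, so it was called moved beyond 5%. Contig and junction coordinates were not joined with the gene tables because the builds differ.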

Results

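RNA labelled as polyadenylated was sequenced from the thymus of 8-week-old C57BL/6J mice, an inbred laboratory strain, in 2 libraries that the labels name biological replicates 1 and 2 of 1 group. The thymus is the organ in which T cells develop: thymocytes rearrange their antigen receptor genes, pass through a stage that carries both the Cd4 and Cd8 co-receptors, and are selected on epithelial, dendritic and other stromal cells. Both samples are labelled as pooled from males and females. The series holds 1 tissue, 1 age and 1 strain, so the data describe the thymus and compare the 2 libraries with each other, not conditions. The gene tables held 49.3 M estimated fragments in replicate 1 and 63.1 M in replicate 2. Intervals and floors given below cover counting error only, and with n = 2 every SD rests on a single difference. Positions are on GRCm38 (mm10) with GENCODE M21 gene models, except for contigs and splice junctions, which the authors deposited on mm9.

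At a mean level of at least 1 TPM, the authors' length-scaled abundance, 14360 of 43346 genes were detected, of which 12949 were protein-coding and 540 long non-coding. Each library by itself held 14302 ± 167 such genes (SD, n = 2). Small structured RNAs and cytoskeletal, translation and T cell receptor transcripts led the table. Rn7sk, the 7SK RNA that restrains transcription elongation (chromosome 9, 78175303 to 78175633), stood at 66474 ± 21679 TPM. Gm42418 (chromosome 17, 39846958 to 39848788), which GENCODE M21 classes as long non-coding, stood at 25495 ± 3191 TPM, and the origin of its reads was not tested. They were followed by the near-identical 7SL genes Rn7s1 and Rn7s2 at 8770.5 TPM each, Gm29216 at 7829 TPM, Actb at 6638 TPM, and Rmrp, the RNA of an RNA-processing ribonucleoprotein, at 5903 TPM. Hist1h2af, Gm26917, Tuba1b, Eef1a1, Trbc1, Gapdh, Atp5b and Hist1h2ap completed the 15 highest symbols outside the mitochondrial and ribosomal protein genes, with means from 4109 down to 3270.1 TPM. Mitochondrial genes took 2.74% of TPM in replicate 1 and 3.68% in replicate 2, and ribosomal protein genes 7.95% and 8.26%. Rn7sk took 5.11% and 8.18%, and Gm42418 with its neighbour Gm26917 3.29% and 2.58%. Reads of Rn7s1 and Rn7s2, and of Gm29216 and the mitochondrial genome, can fall on near-identical copies, so the split between copies is uncertain. Rn7sk, the 7SL genes and Rmrp are made without poly(A) tails, although the labels describe polyadenylated RNA, and the TPM of very short genes is unstable.

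The receptor of T cells was a prominent signature. Trbc1 and Trbc2, the beta chain constant regions on chromosome 6, reached 3551 ± 186 and 3009.5 ± 143 TPM (SD, n = 2 here and for every ± below), although these near-identical genes share reads. Cd247, Cd3e, Cd3d and Cd3g, the CD3 signalling chains, stood at 496 ± 39.5, 305 ± 71.01, 235 ± 24.8 and 159 ± 13.6 TPM, and Trac, the alpha chain constant region, at 399 ± 30.5 TPM. Ptcra, the surrogate alpha chain of immature thymocytes, was at 118 ± 26.1 TPM. The gamma chain constant genes were far lower, with Tcrg-C1 at 9.32 ± 0.297, Tcrg-C2 at 5.19 ± 0.933 and Tcrg-C4 at 3.67 ± 0.665 TPM. The median of this list, 235 TPM over 11 genes, lay above every one of 10000 random lists of equal size. The receptor signalling list (17 genes, all at 10 TPM or more) had a median of 118 TPM, led by Lck at 1391 ± 90.04 and Lat at 1265 ± 71.7 TPM, a kinase and an adaptor close to the receptor, followed by Ptprc at 389, Cd6 at 258 and Zap70 at 227 TPM.

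Genes of the list of receptor rearrangement and the double positive stage stood higher than those of the early, double negative thymocyte list. The rearrangement and double positive list had a median of 296 TPM over 17 genes, led by Satb1 at 780.4 ± 131, Cd8b1 at 627 ± 58.8, Arpp21 at 513 ± 38.8, Cd8a at 503 ± 16.9 and Cd4 at 453 ± 9.96 TPM. The recombinase genes Rag1 and Rag2 were at 276 ± 0.481 and 39.5 ± 6.35 TPM, and Dntt, which adds untemplated nucleotides at the joins, at 296 ± 16.6 TPM. The early thymocyte list had a median of 15.5 TPM over 16 genes, of which 9 reached 10 TPM. Its highest members were Tcf7 (2523 ± 317 TPM), Bcl11b (374 ± 142), Notch1 (156 ± 40.9), Gata3 (85.6 ± 25.3) and Notch3 (52.4 ± 5.66 TPM), and Tcf7, Bcl11b and Gata3 are also used after that stage. The mean log2(TPM + 1) was 7.70 in the first list and 4.66 in the other, a difference of 3.04 or 8.21-fold (two-sided permutation test across genes, raw p = 0.000800, adjusted p = 0.00480 over 6 list pairs). Genes are not independent replicates, and the test compares gene lists within this tissue. It depends on which genes each list holds and does not compare amounts of cells at each stage.

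Helper and cytotoxic lineage lists did not pass that test. The CD4 list had a median of 53.2 TPM over 8 genes, with Gata3, Tox (66.4 ± 10.6), Izumo1r (55.7 ± 0.177) and Zbtb7b (50.7 ± 1.00 TPM) behind Cd4. The CD8 list had a median of 21.8 TPM over 10 genes, with Ccl5 (527 ± 122), Nkg7 (49.03 ± 3.89) and Runx3 (23.9 ± 6.53 TPM) beside Cd8b1 and Cd8a. The difference was 0.55 on the log2 scale (two-sided exact permutation test across genes, raw p = 0.715, adjusted p = 0.715), 0.12 with members of at least 1 TPM only and 1.22 as CPM, neither of which passed. The transcription factors of T cell fate were all at 10 TPM or more, with a median of 219 TPM over 20 genes, and Tcf7, Satb1, Ikzf1 (639 ± 187), Bcl11b and Tcf12 (331 ± 5.39 TPM) were highest. Genes of selection, maturation and egress had a median of 51.4 TPM over 18 genes, led by the chemokine receptors Cxcr4 (980.2 ± 119) and Ccr9 (457 ± 44.2), then Cd5 (196 ± 9.24), Ccr7 (179 ± 14.3) and the activation gene Egr1 (129.5 ± 33.8 TPM). Regulatory T cell genes had a median of 10.97 TPM over 9 genes, with Tnfrsf18 at 67.97, Tnfrsf4 at 60.9, Il2ra at 15.96, Ikzf2 at 12.7 and Tnfrsf9 at 10.97 TPM. The early thymocyte list also holds Il2ra, and Foxp3 was the lowest member at 4.185 TPM. The list of natural killer T, gamma-delta and innate lymphoid cells had a median of 3.27 TPM over 13 genes, of which 9 reached 1 TPM. Gata3, which other lists also hold, Il17rb (29.7), Sox13 (16.1), Tcrg-C1 and Blk (4.71 TPM) were its highest members.

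Cell division genes were abundant. The S phase list had a median of 83.8 TPM over 18 genes, with the replication clamp Pcna at 347 ± 65.5, Uhrf1 at 169 ± 66.7, Mcm7 at 167 ± 33.2, Mcm2 at 136 ± 38.2 and Mcm5 at 132 ± 29.8 TPM. The list of G2 and M phase genes had a median of 56.6 TPM over 18 genes, with Ube2c at 311 ± 74.9, Ccna2 at 226 ± 103, Aurkb at 194 ± 56.9, Cdc20 at 148.1 and Cdk1 at 119 ± 20.2 TPM. These lists differed by 0.53 on the log2 scale, which did not pass the test (permutation test, raw p = 0.353, adjusted p = 0.501). Replication-dependent histone genes had a median of 168 TPM over 15 genes, led by Hist2h3c2 at 1096 ± 411, Hist1h4d at 496 ± 34.6, Hist1h3b at 416 ± 32.4, Hist1h2ab at 298 ± 128 and Hist1h2bc at 259.9 ± 14.7 TPM. Most mRNAs of this class end without a poly(A) tail. Genes of involution and apoptosis had a median of 47.96 TPM over 13 genes, with Bcl2l1 at 169, Mcl1 at 143, the glucocorticoid target Fkbp5 at 135, Bax at 97.6 and Tsc22d3 at 68.5 TPM.

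Transcripts of both epithelial compartments of the thymus were detected. The cortical epithelium list had a median of 74.3 TPM over 15 genes, led by Tbata (678 ± 103), Prss16 (669 ± 187), a protease of cortical epithelium, the chemokine Cxcl12 (230.2 ± 21.3), Krt8 (217 ± 22.3) and Ctsl (180.5 ± 68.2 TPM). The medullary list had a median of 37.2 TPM over 16 genes, with H2-Aa (964 ± 151), also made by dendritic and B cells, Ccl21a (409 ± 40.9), Krt17 (208 ± 13.2), Krt5 (126 ± 11.5) and Aire (71.99 ± 2.45 TPM), the regulator of promiscuous antigen expression. The difference of 0.68 on the log2 scale did not pass the test (permutation test, raw p = 0.418, adjusted p = 0.501), nor did that of 1.22 as CPM. Mimetic and specialised epithelial genes were near the detection limit, with a median of 0.963 TPM over 18 genes, 8 of them at 1 TPM or more, and Spib (29.3), Gp2 (7.63), Chga (6.61), Foxj1 (5.64) and Krt10 (4.46 TPM) on top. Antigens of other organs had a median of 1.49 TPM over 22 genes, with Mbp (49.2), Csn2 (28.3), Alb (22.2), Tff3 (8.31) and Apoa1 (6.78 TPM) highest on average, and 5 under 0.1 TPM in both libraries. The place of Alb and Apoa1 rested on replicate 1, where Alb had 44.2 and Apoa1 10.95 TPM, against 0.180 and 2.60 TPM in replicate 2, and without replicate 1 the median of the list was 0.955 TPM. Parathyroid and thyroid genes were lower still, at a median of 0.210 TPM over 11 genes, with Pth (4.14), Calca (3.08) and Tg (1.48) at 1 TPM or more, and Tshr and Casr at 0.880 and 0.780 TPM.

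Among the lists of other cell types, Cd74 and H2-Ab1 of the dendritic cell list were the highest single genes, while the fat list had the highest median. The dendritic cell list had a median of 31.99 TPM over 16 genes, with Cd74 (2789 ± 282), H2-Ab1 (2557 ± 594), Ly6d (985 ± 154), H2-Aa and Bst2 (371 ± 4.94 TPM). Other lists also hold H2-Aa and Bst2, 10 of the 16 genes reached 10 TPM, and Cd209a was lowest at 1.07 TPM. The list of B and plasma cells had a median of 7.01 TPM over 15 genes, with Igkc (1284 ± 493), Ighm (917 ± 144), Jchain (48.5 ± 20.1), Cd79a (33.5 ± 4.72) and Cd79b (29.7 ± 4.95 TPM), a difference of -1.68 on the log2 scale against dendritic cells (permutation test, raw p = 0.159, adjusted p = 0.318). The macrophage list had a median of 16.8 TPM over 14 genes, with Lyz2 (331 ± 95.1), the complement genes C1qc (324 ± 62.6), C1qb (267 ± 62.6) and C1qa (179.9 ± 32.7), and Cd68 (88.3 ± 5.41 TPM). The granulocyte list had a median of 3.54 TPM over 15 genes, with Camp (20.5), S100a8 (16.3), Ngp (13.1), S100a9 (11.4) and Csf3r (5.67 TPM). Macrophage genes exceeded granulocyte genes by 2.15 on the log2 scale, or 4.44-fold (permutation test, raw p = 0.00942, adjusted p = 0.0283), by 2.90 as CPM and by 1.94 without replicate 2. Fibroblast and mesenchyme genes had a median of 13.8 TPM over 12 genes, with Thy1 (1768 ± 130.2 TPM), which thymocytes also express, Dcn (54.9), Igf1 (47.3), Dpp4 (17.6) and Col1a2 (17.3 TPM). Endothelial and pericyte genes had a median of 3.89 TPM over 13 genes, with Acta2 (109), Eng (52.1), Pecam1 (46.6), Vwf (20.9) and Cdh5 (11.7 TPM). Fat genes had a median of 48.3 TPM over 14 genes, with Cfd (750.0 ± 98.7), Scd1 (314 ± 102), Car3 (276 ± 26.3), Ucp1 (235 ± 157) and Cidec (88.8 ± 11.2 TPM). The erythroid and blood list had a median of 10.4 TPM over 10 genes, with the globins Hba-a2 (1979 ± 146), Hbb-bs (1561 ± 354), Hba-a1 (1243 ± 135) and Hbb-bt (188 ± 48.5) and the platelet gene Pf4 (12.5 ± 6.80 TPM), where the alpha globin genes are near-identical and share reads.

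**Figure D1:**
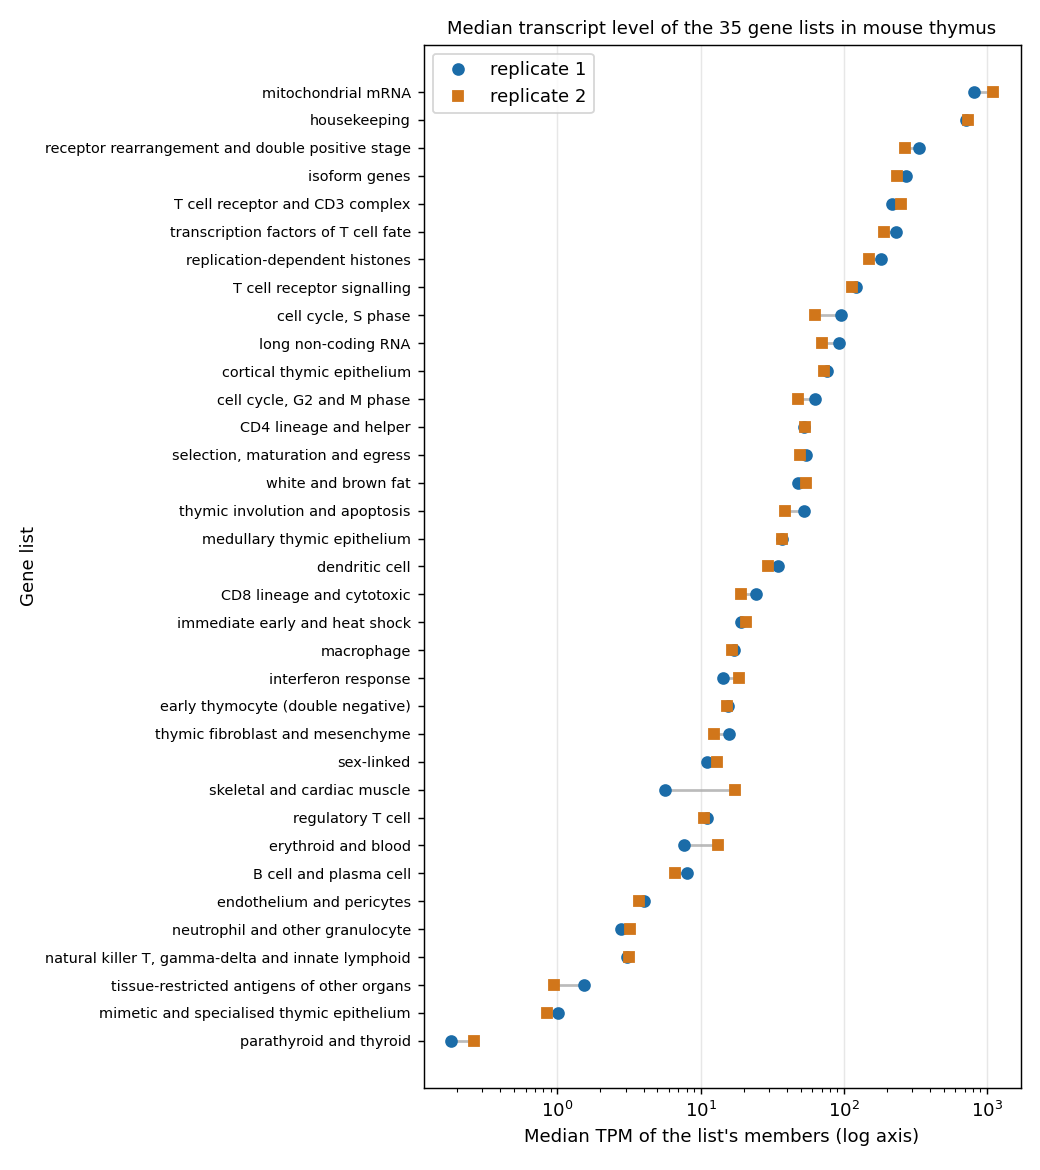
Median TPM (log axis) of the members of each of the 35 gene lists, with circles for replicate 1 and squares for replicate 2, joined by a grey line. Mitochondrial and housekeeping genes lie highest, parathyroid and thyroid genes lowest, and the skeletal and cardiac muscle list shows a wide gap, from 5.64 TPM in replicate 1 to 17.5 TPM in replicate 2.

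Stress and state lists were intermediate. Immediate early and heat shock genes had a median of 19.95 TPM over 13 genes, with Zfp36 (192), Egr1, Junb (101), Dnajb1 (97.7) and Dusp1 (45.9 TPM), and interferon response genes one of 16.4 TPM over 14 genes, with Bst2, Irf7 (207), Cxcl10 (77.05) and Isg15 (37.2 TPM). Housekeeping genes had a median of 725 TPM over 14 genes, and Eef2 (1634) and Tubb5 (1457 TPM) followed Actb, Eef1a1 and Gapdh. Mitochondrial mRNAs had a median of 959 TPM over 13 genes, with mt-Co1 (9031 ± 2665), mt-Atp8 (7969 ± 425), mt-Co3 (5561 ± 2513), mt-Atp6 (2324 ± 367) and mt-Cytb (2120.0 ± 169 TPM). The TPM of mt-Atp8 came from only 599 and 775 fragments on a very short gene. The long non-coding list had a median of 81.3 TPM over 12 genes, with Rmrp, Rpph1 (3234 ± 809), the RNA of ribonuclease P, Malat1 (282 ± 19.3), Neat1 (221 ± 12.7) and Mir142hg (119 ± 29.4 TPM). Over the whole annotation, the 10 highest long non-coding genes were Gm42418, Gm26917, Gm10076 (852 ± 89.2), Malat1, Neat1, Dgkeos (199.8 ± 49.4), 2410006H16Rik (191 ± 48.6), Tmem134 (166 ± 5.59), 1810058I24Rik (145 ± 2.54) and Gm42743 (139.6 ± 1.73 TPM), by the gene classes of GENCODE M21. The origin of the reads of the neighbours Gm42418 and Gm26917 was not tested, so their rank may not reflect long non-coding RNA. The isoform list had a median of 253 TPM over 30 genes, among them Ptma at 2163 and Pkm at 763 TPM. Of 455 list genes, 14 were under 0.1 TPM in both libraries. Without length scaling, as CPM, the medians of most lists moved by more than 1.5 times, among them histones to 30.8, fibroblasts to 46.4, endothelium to 18.7 and the sex-linked list to 41.6 CPM. In all, 28 of the 35 lists had a median of at least 10 TPM.

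Usage of T cell receptor beta V segments was concentrated on a few genes. Of the Trbv counts (11489 in replicate 1 and 16288 in replicate 2, 34 genes on chromosome 6), Trbv31 held 17.8% (17.1 to 18.5%) in replicate 1 and 17.6% (17.01 to 18.2%) in replicate 2, with 95% exact binomial intervals in brackets. Trbv13-2 held 13.6% (12.98 to 14.2%) and 13.3% (12.8 to 13.9%), Trbv13-1 13.4% (12.8 to 14.1%) and 13.4% (12.9 to 13.95%), Trbv1 12.8% (12.2 to 13.4%) and 13.4% (12.9 to 13.97%), and Trbv16 10.1% (9.60 to 10.7%) and 10.9% (10.4 to 11.3%). The intervals of the 2 libraries overlapped for each of these 5 segments, but not for Trbv15, chosen after its values were seen, with 3.53% (3.20 to 3.88%) and 4.22% (3.92 to 4.54%). By TPM, which divides by effective length, the order changed, with Trbv13-2 at 18.3%, Trbv13-1 at 15.1% and Trbv31 at 14.9%. Trbv31 lies at chromosome 6, 41557691 to 41558452. Counts are per gene and do not tell productive from unproductive joins.

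**Figure D2:**
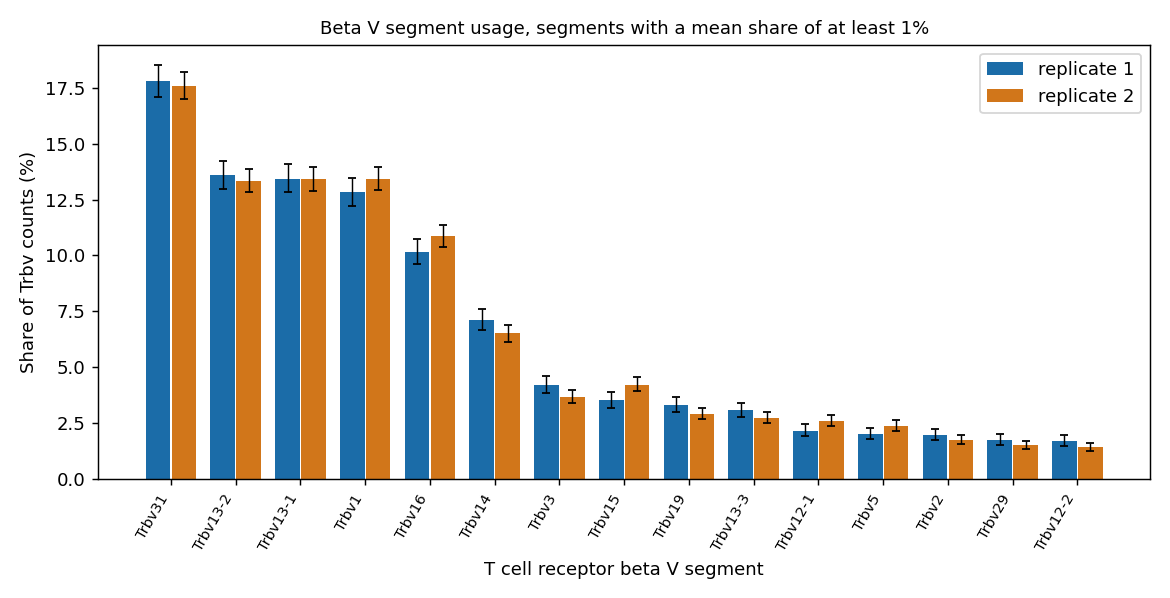
Share of each beta V segment in all Trbv counts (%), bars for replicate 1 and replicate 2, for segments with a mean share of at least 1%. Error bars are 95% exact binomial intervals (counting error only), and Trbv31 leads with 17.8 and 17.6%.

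Most genes used several annotated transcripts. Over 9851 genes with a mean of at least 1 TPM and 2 or more annotated transcripts, the highest transcript took a median of 67.03% of its gene's TPM. It took over 90% in 22.2% of genes and under 50% in 24.1%, and the libraries shared the same highest transcript in 88.3%. Named by GENCODE M21, Cd4-201 took 93.3 ± 0.552% of Cd4, Pkm-201 92.2 ± 4.12%, Dntt-202 90.3 ± 2.67%, Bcl2l1-201 83.9 ± 3.29% and Rag2-202 81.8 ± 1.81%. Bcl2l11-205 (75.3 ± 7.27%), Ptma-202 (74.8 ± 0.409%), Runx1-203 (74.3 ± 4.27%), Bcl11b-203 (70.5 ± 6.02%), Ikzf1-201 (66.9 ± 8.32%) and Satb1-203 (63.7 ± 0.530%) also led their genes. Shares were more even for Tcf7, with 54.7 ± 2.37% for Tcf7-201, Lef1, with 52.9 ± 3.65% for Lef1-201, Gata3, with 51.8 ± 0.204% for Gata3-202, Cd8a, with 50.6 ± 0.599% for Cd8a-201, and Lck, with 49.5 ± 2.09% for Lck-201. The libraries differed in the leading transcript of Fyn, with Fyn-201 at 65.3% in replicate 1 and Fyn-206 at 45.2% in replicate 2, of Mcl1, with Mcl1-202 at 60.8% and Mcl1-201 at 51.2%, and of Runx3, with Runx3-202 at 60.3% and Runx3-201 at 49.3%. The remaining leading transcripts were those of Cd44 (Cd44-203, 54.1 ± 1.85%), Ikzf2 (Ikzf2-201, 50.6 ± 11.5%), Tpm3 (Tpm3-201, 49.3 ± 1.64%), Hnrnpa2b1 (Hnrnpa2b1-203, 44.7 ± 13.8%), Ptprc (Ptprc-213, 43.5 ± 3.22%), Tcf12 (Tcf12-210, 39.4 ± 0.783%) and Tcf3 (Tcf3-202, 33.9 ± 3.56%), while Ptcra, Cd8b1 and Rag1 had a single transcript. The deposited estimates split reads between isoforms by a model, and short annotated fragments such as Ptprc-213, of 702 bases, can draw TPM from longer forms.

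The libraries were close for most genes. Across the 14360 detected genes, Pearson's r of log2(TPM + 1) was 0.977 and Spearman's rho 0.975 (across genes, which are not independent replicates). Of 14280 detected genes with a symbol of their own, 95.8% lay within 2-fold. The biological coefficient of variation, from edgeR's common dispersion over 17198 genes, was 0.214, against 0.0728 from DESeq2's median gene-wise dispersion. Spike-in RNAs took 1.49% and 1.48% of fragments (2.32% of TPM on average), and over the 68 spike-ins seen in both libraries the r of log2 TPM was 0.993.

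Myl3, Nppa and Pln, genes of heart muscle, were far higher in replicate 2, and Alb, Apoa2 and Ahsg, genes of the liver, in replicate 1. The exact binomial test of the counts of each gene, which compares these 2 libraries and not conditions, called 780 of 17198 genes (Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), 571 higher in replicate 2 and 209 higher in replicate 1. Counts simulated at the measured coefficient of variation, re-estimated as 0.254, gave 631 false calls in this test. Counts simulated at 0.15, re-estimated as 0.206, gave 134. So some or many of the 780 calls, and of those in the gene lists, can come from typical spread, and 2 libraries cannot settle how many. The negative binomial test takes its dispersion from the same 2 libraries, with no replicate of either, so it does not measure spread within a condition. With a negative binomial test at the common dispersion, edgeR called 219, of which 169 were higher in replicate 2 and 50 in replicate 1. Among genes kept by the filter on low counts and with a mean count of at least 50, the 5 highest in replicate 2 were Myl3, a myosin light chain (chromosome 9, 110741861 to 110769798; 52 and 8199 counts, log2 ratio 6.86), Nppa, the atrial natriuretic peptide (31 and 4857 counts, 6.84), Lrtm1 (13 and 669 counts, 5.20), Pln, phospholamban (144 and 6985 counts, 5.16), and Lrrc10 (17 and 711 counts, 4.91). Their adjusted p from edgeR's negative binomial test was at most 2.11e-14. Among the same genes, the 5 highest in replicate 1 were Alb, serum albumin (chromosome 5, 90460897 to 90476602; 2831 and 16 counts, log2 ratio -7.85), Apoa2 (418 and 20 counts, -4.78), Ahsg (1106 and 84 counts, -4.14), the pseudogene Rpl7a-ps11 (219 and 17 counts, -4.08), whose reads can fall on near-identical copies, and Cd209b (171 and 14 counts, -4.00). Their adjusted p from edgeR's negative binomial test was at most 3.30e-09. The histone gene Hist1h2ap was also called, at 5132 and 1409 TPM (log2 ratio -1.83, edgeR's negative binomial adjusted p = 0.00519). The filter required counts in both libraries, so genes close to 0 in 1 library were not tested, and without it 1443 genes were called. Among those it left out were the heart myosin gene Myl2 (8 and 2820 counts, log2 ratio 7.94), above Myl3, and the liver protease inhibitor genes Serpina1c (507 and 6 counts, -6.72) and Serpina3k (245 and 10 counts, -4.98), beyond Apoa2, all chosen after their values were seen.

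Of the fixed lists, skeletal and cardiac muscle differed most, with a median log2 TPM ratio (replicate 2 over replicate 1) of 3.33, above all 10000 expression-matched random lists. Its median was 11.5 TPM over 14 genes, and of 9 members tested 8 were called by the exact binomial test, all higher in replicate 2. Actc1, cardiac actin, had 57.7 and 574 TPM in replicates 1 and 2, Mb, myoglobin, 15.1 and 438 TPM, Ckm, muscle creatine kinase, 10.7 and 163 TPM, Myh6, a cardiac myosin heavy chain, 8.46 and 86.9 TPM, and Tnnt2, cardiac troponin T, 5.57 and 71.3 TPM. With members under 1 TPM included, the median ratio of this list was 1.92. Smaller shifts toward replicate 2 were seen for the erythroid list (median log2 ratio 0.46, percentile 99.97 among random lists), mitochondrial mRNAs (0.28), interferon response genes (0.25, percentile 99.93) and macrophage genes (0.25). The cortical epithelium list (0.19), the long non-coding list (0.19), the medullary list (0.099) and the mimetic epithelium list (0.32, percentile 97.81) also lay above the middle 95% of random lists, the last one not when members under 1 TPM were included (0.21) or those under 5 TPM left out (0.23). The median ratio is taken over members and can differ in sign from the ratio of median levels, which in replicates 1 and 2 were 75.87 and 72.85 TPM for cortical epithelium, 91.9 and 70.6 for the long non-coding list, 1.015 and 0.8500 for mimetic epithelium and 17.1 and 16.6 TPM for macrophages, all lower in replicate 2. Pf4 of the erythroid list was called by the exact binomial test, at 7.70 and 17.3 TPM, but not by edgeR's negative binomial test (adjusted p = 0.4996).

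Shifts toward replicate 1 were seen for proliferation genes and T cell transcription factors. The S phase list had a median log2 ratio of -0.54, below every random list, with all 18 members higher in replicate 1, and the list of G2 and M phase genes -0.40 with 17 of 18. Histones were at -0.30, transcription factors of T cell fate at -0.42 with 18 of 20 members higher in replicate 1, and the isoform genes, which share many of these factors, at -0.28. The exact binomial test called 1 of 18 tested members of the S phase list, 0 of 18 of the list of G2 and M phase genes, 0 of 15 of the histone list, 0 of 20 transcription factors and 0 of 30 isoform genes. Granulocyte genes were at -0.35, and at -0.68 when members under 5 TPM were left out, with 2 of 15 tested members called by the exact binomial test, while the median level was 2.79 and 3.22 TPM in replicates 1 and 2. Antigens of other organs, where 4 of 15 tested members were called by the exact binomial test, Alb and Apoa1 among them, were at -0.27, at -0.51 without members under 5 TPM, and inside the middle 95% with ratios scaled by TMM (-0.14) or by spike-ins (-0.052). These 2 scalings differ by a constant for all genes, so a list has the same percentile under both, here 5.13. Without liver genes, a split chosen after the data were seen, 11 such antigens had a median of -0.010, with 5 higher in replicate 2 and 6 in replicate 1. The receptor and CD3 list was at 0.064 (percentile 88.44). In total 16 of the 35 lists lay outside the middle 95%, 9 above and 7 below. All 16 kept their sign with TMM and with spike-in scaling, under which the median log2 ratio of all tested genes was 0.0062 and 0.096. The percentiles describe these libraries and are no test.

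The remaining 19 lists lay within the middle 95% of random lists, but B and plasma cells left it with members under 1 TPM included (-0.26), and dendritic cells (0.16) and sex-linked genes (-0.40) without members under 5 TPM. Lymphoid medians were -0.13 for early thymocytes, -0.11 for rearrangement and the double positive stage, -0.045 for CD4, 0.051 for CD8, -0.043 for regulatory T cells, -0.11 for selection and egress, 0.064 for natural killer T and gamma-delta cells (-0.19 without members under 5 TPM) and -0.053 for receptor signalling, where spike-in scaling gave 0.013 for the double positive stage, 0.095 for CD4, 0.089 for regulatory T cells, 0.041 for selection and 0.037 for signalling. Other cell types gave -0.0065 for fibroblasts, 0.0033 for endothelium, -0.20 for B and plasma cells, 0.10 for dendritic cells, 0.062 for fat and -0.20 for parathyroid and thyroid genes, and with spike-in scaling fibroblasts were at 0.14 and parathyroid and thyroid genes at 0.28. Members of the list of B and plasma cells went both ways, with log2 ratios of 0.91 for Jchain, 0.83 for Igkc and 0.34 for Ighm against -0.25 for Cd79a and -0.30 for Cd79b, none of these named genes called. Of the 15 tested members of that list, 2 others were called by the exact binomial test. Of these, 1 had at least 1 TPM and was higher in replicate 1. State lists gave -0.092 for immediate early genes, -0.22 for involution and apoptosis, -0.25 for sex-linked and -0.18 for housekeeping genes, with immediate early genes at 0.10 and sex-linked genes at 0.045 under spike-in scaling. Ucp1, the uncoupling protein of brown fat, was called higher in replicate 1 by the exact binomial test, at 346 and 124 TPM, Lep, also of the fat list and chosen after its values were seen, higher in replicate 2, at 1.09 and 2.41 TPM, and Pth higher in replicate 2, at 2.33 and 5.96 TPM. None of them passed edgeR's negative binomial test (adjusted p = 0.0854, 0.5001 and 0.346). In all, 9 lists held a called gene, and adjusted over the list alone the number of called genes was identical in each of the 35 lists.

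**Figure D3:**
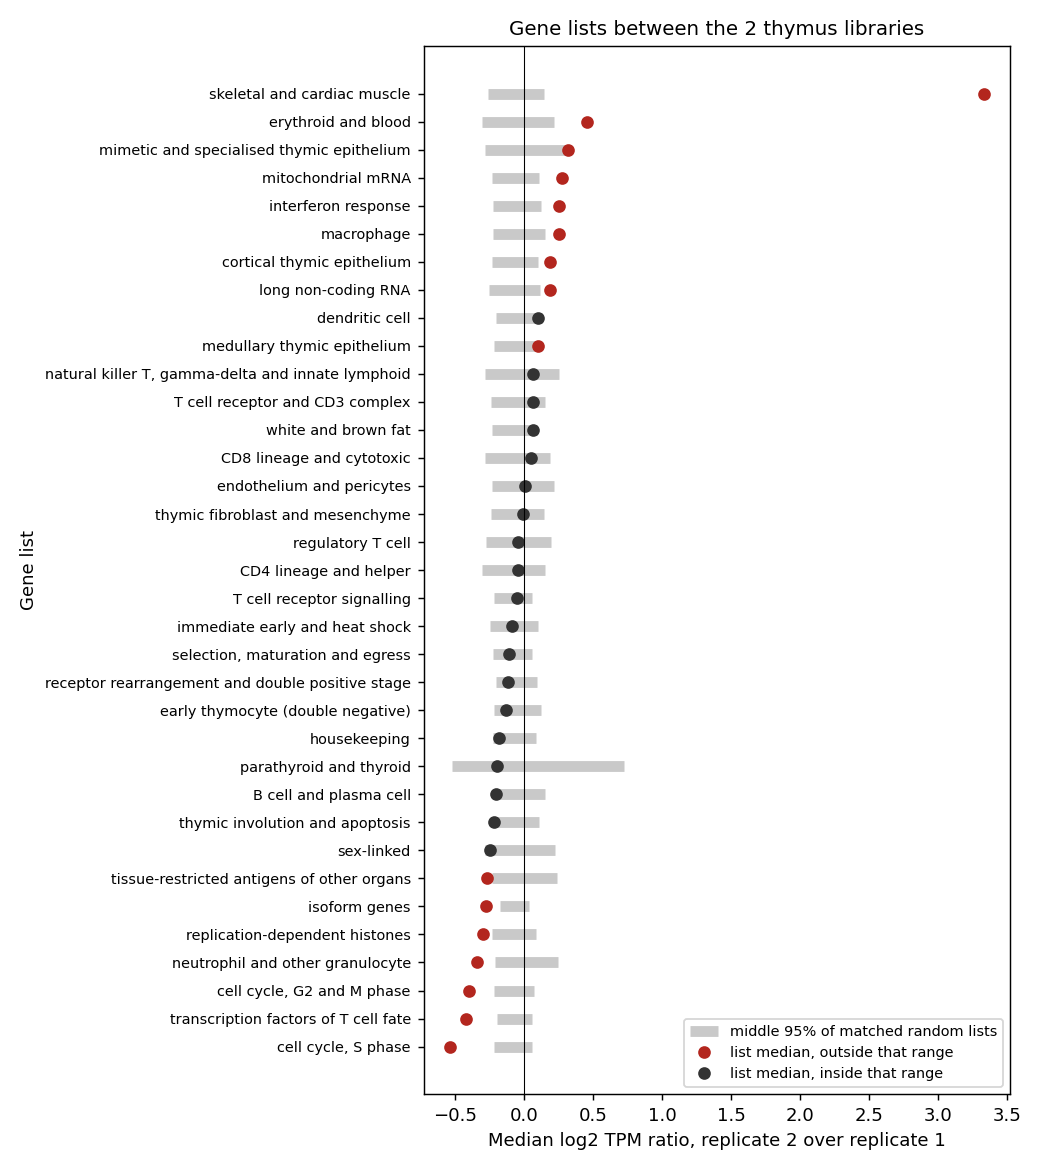
Median log2 TPM ratio of each gene list, replicate 2 over replicate 1, as points, with grey bars for the middle 95% of medians of 10000 expression-matched random lists. The skeletal and cardiac muscle list lies at 3.33, and the S phase list lowest at -0.54.

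The sex-linked list had a median of 12.04 TPM over 10 genes and separated the libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in replicate 1 and 439, 376, 1717 and 484 counts in replicate 2, where they reached 2.61, 2.64, 7.53 and 5.50 TPM. Against the floor of 3 counts in replicate 1, after scaling for depth, Kdm5d was at least 424-fold higher in replicate 2 and Uty at least 92.9-fold. The filter left these genes out of the main test, and in the exact binomial test without it all 4 were called, with adjusted p of at most 1.82e-89. Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254), had 86.9 TPM in replicate 1 and 52.8 in replicate 2, a log2 ratio of -0.68 that did not reach 2-fold. The X-linked genes Kdm5c (95.8 and 72.8 TPM), Eif2s3x (69.5 and 53.4), Ddx3x (40.03 and 28.5) and Kdm6a (22.1 and 18.6 TPM) were not called either, and Tsix was under 0.1 TPM in both libraries.

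**Figure D4:**
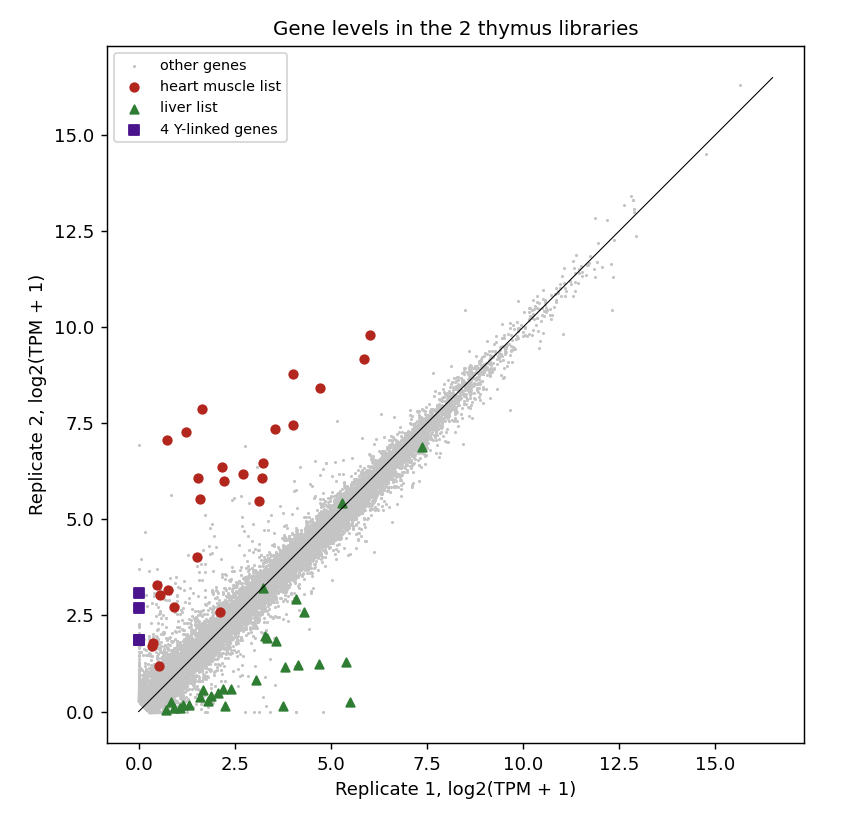
Gene levels in replicate 1 (x axis) and replicate 2 (y axis), both as log2(TPM + 1), for genes with a mean of at least 0.1 TPM, with the line of equality. Circles mark 26 heart muscle genes and triangles 29 liver genes, lists chosen after the data were seen, and squares mark the 4 Y-linked genes, which lie at 0 in replicate 1.

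The series-level list of contigs, stretches of the genome covered by reads of both replicates together, held 777779 contigs on mm9, 395616 on the plus and 382163 on the minus strand. Their median length was 241 bases, the longest had 31585 bases, and together they covered 331 megabases. The authors' level was highest for a contig of 435 bases at chromosome 16, 11143987 to 11144421, plus strand, at 30700. It was followed by chromosome 19, 8326702 to 8326816 (8940), chromosome 9, 110183743 to 110183889 (7900), chromosome 17, 39979936 to 39985795 (6800), and chromosome 9, 78023099 to 78023440 (5760). The contig on chromosome 17, of 5860 bases, held 4.03% of all read bases. At a reproducibility value of at most 0.1 the list held 415523 contigs. On the Y chromosome 54 contigs were listed.

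The junction list held 532115 splice junctions with 38.9 M reads, 267838 on the plus and 264277 on the minus strand. Junctions with a single read made up 44.2% of the list and 0.605% of the reads, and the 137243 junctions with at least 10 reads held 97.95% of the reads. At a reproducibility value of at most 0.1 there were 153487 junctions. The median intron was 1708 bases long, 1186 for junctions with at least 10 reads and 4772 for those with a single read. The most used junction spanned chromosome 5, 143667156 to 143667242, minus strand, with 111553 reads, and the next ones chromosome 5, 143667372 to 143668330 (110033 reads), chromosome 11, 48614075 to 48615164 (107781 reads), chromosome 9, 43851560 to 43854039 (73878 reads), and chromosome 5, 143666462 to 143666915 (69178 reads). An edge of 6.35% of contigs fell exactly on a junction end on the same strand (95% exact binomial interval 6.29 to 6.40%), 11.4% came within 10 bases of one, and 97.6% of contigs overlapped an intron by at least 1 base. Since 1 base is enough, that last share does not say how many contigs are intronic. No gene annotation on mm9 was used here, so these features carry no gene names.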

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

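Replicate 2 held 93 fragments on the phiX control genome, a viral DNA commonly added to sequencing runs, and replicate 1 held 0. This signal lies in a feature that no comparison of the report uses, and is above the 3 counts that a count of 0 allows. No explanation was tested.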

How the results depend on the processing

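All alternatives were planned before the data were examined. Of the results that answer a question, 122 alternative values kept their direction and side of the threshold, moved by less than the spread or, for counts, stayed within 1.5 times, among them the 6 list pairs under each of their 5 alternatives and the number of lists outside the middle 95%, which was 15 to 17 against 16. The number of detected genes followed its criterion beyond the spread between libraries, with 19611 at 0.1 TPM, 10342 at 5 TPM, 17187 with at least 10 counts in both libraries and 15159 by posterior mean TPM. Calls between libraries depended most on the filter and on the error model: without a filter 1443 genes differed (958 higher in replicate 2, 485 in replicate 1), and under the negative binomial model 219 (169 and 50), because that model adds the spread between libraries to counting error. That spread was itself estimated from the 2 libraries compared, so the negative binomial test has no replicates behind it. The coefficient of variation was 0.251 without a filter and 0.0728 from DESeq2's median gene-wise dispersion. Agreement was 0.992 without a filter, 0.9695 at 5 TPM, 0.965 with a pseudocount of 0.1, 0.979 with posterior mean TPM and 0.984 with depth-scaled counts. The mimetic epithelium list, at 0.21 without a filter and 0.23 at 5 TPM, and antigens of other organs, at -0.14 with TMM and -0.052 with spike-ins, came inside the middle 95%, and the cause was not tested. For list percentiles, TMM and spike-in scaling give the same result by construction, although the numbers of alternative values given here count both. By TPM, Trbv31 had 14.9% and spike-ins 2.32%. The leading transcript took 76.9% by expected counts, 63.8% by posterior mean TPM, 64.99% at 10 TPM, and 67.7 to 67.9% when a replicate was left out. Contigs numbered 415523 and 282757 at reproducibility values of at most 0.1 and 0.01, and 386537 above the median level. Junctions numbered 153487 and 122626 at these values, and 137243 with at least 10 reads. An edge within 10 bases of a junction end was found for 11.4% of contigs, and the planned count of contigs that overlap an intron anywhere, which is another quantity, gave 97.6%. For these counts and shares the stricter or looser criterion itself sets the change. Of single list values, 232 kept their side or their spread, 55 moved and 3 left the middle 95%: B and plasma cells without a filter, and dendritic cells and sex-linked genes at 5 TPM. The parathyroid and thyroid list had no member at 5 TPM and no value there. No paired analysis was possible because the series has 1 group. Depth can limit those genes near 1 TPM and those isoform shares where few fragments decide, which was not tested.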

Other observations

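All tests in this part were chosen after the result was seen. Receptor segments beyond the beta chain were also expressed. Of 103 Trav genes, the alpha chain V segments, 87 had a mean of at least 1 TPM, and their summed level was 675 ± 61.9 TPM (SD, n = 2), against 1969.6 ± 42.5 for Trbv. The highest Trav share of counts was 5.66 ± 0.364% for Trav8-2, classed as a pseudogene, which had 0.437% by TPM, and the next was Trav3-3 with 5.16 ± 0.178%. Trdv and Tcrg-V segments were far lower, at 25.95 ± 1.38 and 5.95 ± 0.0778 TPM. Immunoglobulin V segments were present as well, with 173 Ighv genes at a sum of 252 TPM in replicate 1 and 406 in replicate 2, and 103 Igkv genes at 347 and 590.2 TPM.

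Heart muscle genes were higher in replicate 2. Over 26 heart genes, 5 of them also in the fixed muscle list, the median log2 ratio was 3.76, 18 had at least 1 TPM in replicate 1 too, and Tnni3 (63.6 and 898 TPM) and Actc1 (57.7 and 574 TPM) were the most abundant. Thymic myoid cells, which carry skeletal muscle genes, are argued against: summed counts of 8 skeletal and myoid genes differed by 0.48 (95% exact binomial interval 0.22 to 0.75), and by 1.15 (0.65 to 1.69) without Mylpf. A candidate source is heart tissue RNA in the replicate 2 sample: 15 heart genes whose ratios had not been read had a median of 3.18, and all 15 were higher in replicate 2. The SE of the mean over these genes was 0.28. It treats genes as independent and measures no spread between samples. These 15 genes are part of the 26, so they show how widely heart genes moved and not where the RNA came from. Whether heart RNA came in at dissection or otherwise stays open, and no biological explanation other than myoid cells was tested.

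Liver genes were higher in replicate 1. Over 29 liver genes, 4 of them also in the fixed list of antigens of other organs, the median log2 ratio was -3.17, 12 had at least 1 TPM in replicate 2 too, and Trf (164 and 116 TPM), Alb (44.2 and 0.180 TPM) and Apoa2 (41.4 and 1.46 TPM) were the most abundant in replicate 1. A general change in promiscuous expression by thymic epithelium, which makes antigens of other organs, is argued against, since 11 such antigens without liver had a median of -0.010, above the liver median by 3.16, with a spread over members of 1.32. Liver tissue RNA in the replicate 1 sample may account for it: 21 liver genes whose ratios had not been read had a median of -2.76, although Trf, the most abundant of them, Hp and Cyp2e1 did not follow (log2 ratios -0.22, 0.19 and 0.033). The SE of the mean over the 21 genes was 0.31. It treats genes as independent and measures no spread between samples. These 21 genes are part of the 29, so they show how widely liver genes moved and not where the RNA came from. No biological explanation other than promiscuous expression was tested.

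Counts of 4 Y-linked genes were 0 in replicate 1 although both samples are labelled as pooled from both sexes. Lower depth is argued against: 2236 counts of the 4 genes were expected in replicate 1 at the level of replicate 2, and 0 were found, which allows up to 0.134% of that level. Reads given to X-linked paralogs are argued against as well, since the posterior mean counts of the 4 genes in replicate 1 also summed to 0. Replicate 1 may hold little or no male RNA, to which Xist adds little: its log2 ratio of -0.68 lay beyond the spread of 0.40 from the common dispersion but close to the SD over all genes of 0.60, while all genes on the Y chromosome together had 5 counts in replicate 1 and 3072 in replicate 2. Whether the label or the pooling differs from the sample stays open, and no biological explanation was tested.

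Glycam1, chosen here after its values were seen, had 383 counts in replicate 1 and 0 in replicate 2. The mitochondrial gene mt-Nd3, chosen likewise, had 0 and 781 counts, with 39.7 posterior mean counts in replicate 1.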
